A study of Mus musculus with 12 samples.

How the data were processed

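The series holds 12 libraries of 2 mouse uterine carcinosarcoma lines, in 4 groups of 3. Per the labels' protocols, 4 ug of DNase-treated total RNA went into a stranded, poly-A-selected library and 75 bp single-end reads were sequenced. The submitters' processing notes name FastQC 0.11.2, TopHat2 2.0.12, Picard 1.127, featureCounts, Subread and edgeR, with the mm10 build. Their roles and settings are not given in the sources used here. The values the authors deposited are TPM, since each library sums to 1000000 over 20328 gene symbols. The columns name a group and a library number that the sample labels do not carry, so libraries were assigned to groups and not to replicate numbers. No column was left unmatched.

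The planned count test needs counts, and the deposited unit is TPM, so the alternative fixed for that case was used. Genes with a mean of at least 1 TPM over the 12 libraries (12050 genes) were tested on log2(TPM + 1), a pseudocount of 1, with limma 3.58.1 in R 4.3.3. All libraries entered 1 fit with 4 groups and 1 spread per gene, moderated with a trend on expression, and p values were adjusted by Benjamini-Hochberg at an FDR of 0.05. The contrasts were FBXW7 against control in each line, their mean, their difference (UCS2 effect minus UCS1 effect) and UCS2 control against UCS1 control. The groups turned out to spread unequally, so each line was also fitted alone.

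Depth was recovered from the values. Each TPM was a whole number of reads divided by a gene length and scaled per library, within 0.05 reads, for 100% of the 18484 genes above 0. This gave 20935670 to 36196850 assigned reads per library. Replicates were compared with a chi-square test on these reads. The statistic per degree of freedom was 2.13 to 6.52 in UCS1 pairs and 14.75 to 124.44 in UCS2 pairs, where counting noise alone gives about 1, so no pair was treated as 1 library deposited again. This does not show that the libraries came from separate cultures, since repeat libraries of 1 RNA also exceed counting noise. The series calls the libraries biological replicates but does not say that each came from a separate transduction, so p values measure the spread between these libraries.

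The choices of tests, 23 gene lists and named genes were made before the data were examined. Of the lists, 21 had at least 5 tested genes and were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. The mitochondrially encoded list had no gene in the table. Named genes were Fbxw7 and Pten, and per line the 10 genes per direction with the largest log2 fold change among those called, with a mean of at least 2 TPM and no overlap between the groups. Added to these were the 8 per direction with the largest smaller change in both lines, the 6 per direction for differences, and up to 4 called members per list with the smallest p. Predicted genes with Gm or Rik symbols were counted and not named. Coordinates are from GENCODE for the mm10 assembly, 1-based, matched by symbol for 94.6% of the genes.

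The procedure was tested on simulated data of 12050 genes in 10 simulations with the spread of each line, no line difference and 200 genes changed in both lines. The pooled fit recovered 86.4% of genes changed by a log2 of 1 in UCS1 and 86.6% in UCS2. Its false calls made up 0.6% of all calls in UCS1, 56.4% in UCS2 and 15.4% for the mean effect. Fitted alone, UCS1 gave 98.6% recovery and 4.3% false calls, and UCS2 gave 56% and 4%. The pooled fit stayed the main test because it had been fixed beforehand, and the UCS2 counts, lists and leading genes are given with the fit of UCS2 alone. In a simulated list test for UCS1, the planted list was called and 0 of 20 unchanged lists were.

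Alternatives were median-of-ratios and upper quartile scaling, no filter, a stricter filter of 5 TPM in 3 libraries, a pseudocount of 0.1, limma-voom on the recovered reads, each line alone, an FDR of 0.01, a 2-fold minimum and leaving out each library. Others were added after the data were seen: leaving out libraries 7 and 12, weights by group variance, leaving out genes under 200 bp, and the gene lists in each line alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.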

Results

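Gene expression was measured by RNA sequencing in 12 libraries from 2 mouse cell lines, UCS1 and UCS2. The lines were derived from uterine carcinosarcomas, tumours that hold both epithelial and mesenchymal parts, of mice that lacked Fbxw7 and Pten in the endometrial epithelium. Fbxw7 encodes the substrate-recognition subunit of a ubiquitin ligase, and Pten encodes a phosphatase that opposes PI3K signalling. Cells of each line carried a tetracycline activator and either the empty lentiviral vector (control) or the vector with an inducible Fbxw7 (FBXW7), and all were grown with 500 ng/ml doxycycline. There were 3 libraries in each of the 4 groups, described in the series as biological replicates. Libraries 1 to 3 were UCS1 control, 4 to 6 UCS1 FBXW7, 7 to 9 UCS2 control and 10 to 12 UCS2 FBXW7. Between 20935670 and 36196850 reads were assigned to genes per library. Values are given in TPM, a length-corrected share of each library's transcripts, as mean ± SD with n = 3, and log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes.

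The targeted genes were examined first. Fbxw7 (chromosome 3, 84815268 to 84979198, mm10) was at 19.5 ± 1.33 TPM in UCS1 control and 19.4 ± 0.391 TPM in the UCS1 libraries labelled FBXW7. In UCS2 it was at 18.6 ± 1.46 TPM in control and 14.1 ± 1.28 TPM in the libraries labelled FBXW7, a log2 fold change of -0.37 (limma adjusted p = 0.0318 with all libraries in 1 fit and 0.332 with the UCS2 libraries alone). The gene-level reading therefore did not rise with the FBXW7 label in either line, and it does not show which exons or which copy the reads came from. The species and untranslated regions of the transferred gene are not given in the sources used here. All directions below are for libraries labelled FBXW7 against those labelled control. Pten (chromosome 19, 32757497 to 32826160, mm10) was at 24.3 ± 0.0314 TPM in UCS1 control and 28.9 ± 0.387 TPM in UCS1 FBXW7. In UCS2 it was at 25.1 ± 8.11 and 22.3 ± 2.14 TPM, and neither change passed limma with all libraries in 1 fit (adjusted p = 0.334 and 0.644). With each line fitted alone, limma called Pten higher in UCS1 FBXW7 (adjusted p = 0.000561) and not in UCS2 (adjusted p = 0.799).

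The 2 lines differed in how well their libraries matched. The median SD of a gene on the log2 scale was 0.066 in UCS1 control and 0.051 in UCS1 FBXW7, against 0.192 in UCS2 control and 0.19 in UCS2 FBXW7. Library 12, labelled UCS2 FBXW7, lay at a distance of 35.5 to 37.2 log2 units from the UCS1 FBXW7 libraries and at 59.7 and 52.3 from libraries 10 and 11 of its own group. Library 8, labelled UCS2 control, lay at 22.7 to 26.6 from the UCS1 controls and at 48 and 32.4 from libraries 7 and 9. This was not particular to library 8. Library 9 also lay nearer to the UCS1 controls, at 34.6 to 40, than to library 7, at 55.3. Library 7 lay at 45.9 to 49.1 from the UCS1 controls.

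**Figure D1:**
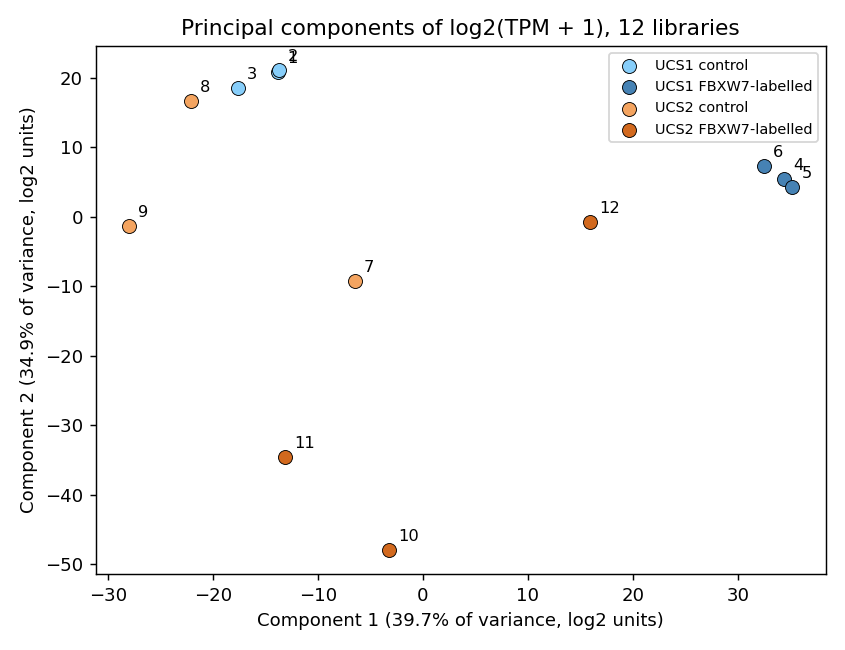
First and second principal components of log2(TPM + 1) over the 12050 genes tested, in log2 units, 1 point per library with its number, coloured by group. The UCS1 groups form tight clusters, whereas the UCS2 libraries are scattered, with library 8 beside the UCS1 controls.

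The comparison in UCS1 asked what the FBXW7 vector changed in that line. Many, but not all, listed genes of the extracellular matrix and of mesenchymal and pericyte cells were higher in the libraries labelled FBXW7. Their lists did not pass camera with an estimated correlation (adjusted p = 0.183, 0.186 and 0.309). They did pass fry (fry adjusted p = 0.000176, 0.000266 and 0.0028). Mgp, a matrix protein that inhibits calcification (chromosome 6, 136872435 to 136875823, mm10), was at 0.366 ± 0.205 TPM in control and 61 ± 3.83 TPM in FBXW7. Ogn, a small leucine-rich proteoglycan (chromosome 13, 49608046 to 49624501), was at 1.9 ± 0.208 and 77.1 ± 5 TPM, and the collagenase gene Mmp13 (chromosome 9, 7272514 to 7283331) was at 36.9 ± 5.48 TPM in FBXW7, a log2 fold change of 4.24. The chemokine gene Cxcl3 was lower, at 13.7 ± 0.916 TPM in control and 2.76 ± 0.568 TPM in FBXW7, and so was Sprr1b, a cornified-envelope gene, at 64 ± 3.6 and 7.95 ± 0.621 TPM.

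By limma, 1565 genes were higher and 1009 lower in UCS1 FBXW7 among 12050 tested at an FDR of 0.05. Of these, 385 and 107 changed at least 2-fold. All 2574 calls were also made when the 6 UCS1 libraries were fitted alone, which called 7525 genes. The fold changes are the same in both fits and the UCS1 libraries spread less than the UCS2 libraries. This agreement is therefore no separate support. Leaving out any 1 of the UCS1 libraries from the pooled fit gave 784 to 943 higher and 341 to 458 lower, the fewest without library 5, and leaving out library 12 gave 2123 and 1611. The split between higher and lower genes depended on the scaling: 60.8% of the calls were higher as deposited and 49.9% after upper quartile scaling. The further genes that rose most were Pde9a, Enpep, Gzme, Fap, Gpx3, Heyl and Serpinf1, with log2 fold changes from 3.67 for Pde9a to 3.33 for Serpinf1. Fap encodes a serine protease of activated fibroblasts and was at 0.164 ± 0.055 TPM in control and 12.1 ± 1.38 TPM in FBXW7. Gpx3, a secreted glutathione peroxidase, was at 2.89 ± 0.519 and 41.5 ± 0.288 TPM. The further genes that fell most were Prl2c2, Snord91a, Itgb7, Snord43, Prl2c3, Prl2c4, Slpi and Sprr2g. Prl2c2, Prl2c3 and Prl2c4 are near-identical prolactin-family paralogs and Sprr2g belongs to a family of similar genes, so their values are uncertain. Snord91a and Snord43 rested on at most 12 and 10 reads per library. The libraries were poly-A-selected, so these values need not reflect the mature small RNAs.

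In the extracellular matrix list, 18 of 25 tested genes were higher in UCS1 FBXW7 and none lower, with 19 higher when adjusted over the list alone. Its mean log2 fold change was 1.20 (camera adjusted p = 4.23e-10; adjusted p = 0.183 with an estimated correlation). Col3a1, a fibrillar collagen (chromosome 1, 45311538 to 45349706, mm10), was at 3.08 ± 0.376 TPM in control and 38.9 ± 2.66 TPM in FBXW7. The elastic-fibre gene Fbln5 had a log2 fold change of 2.34 and Col6a2 one of 2.53. In the mesenchymal list, 18 of 29 genes were higher and none lower, with 19 higher adjusted over the list alone and a mean of 1.03 (camera adjusted p = 4.04e-08; adjusted p = 0.186 with an estimated correlation). Mmp2, Lox, Pdgfra and Pdgfrb were its members with the smallest p, with log2 fold changes of 2.28, 1.49, 2.02 and 2.56. Of 10 smooth muscle and pericyte markers, 6 were higher and none lower, or 9 adjusted over the list alone (camera adjusted p = 2.39e-05; adjusted p = 0.309 with an estimated correlation). Of 20 epithelial genes, 4 were higher and 4 lower, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.289). With UCS1 fitted alone, 22 matrix genes were higher and 2 lower, 24 mesenchymal genes were higher and 4 lower, and 10 pericyte markers were higher and none lower. That fit called 5 epithelial genes higher and 10 lower, or 5 and 11 adjusted over the list alone (camera adjusted p = 0.187). The 4 epithelial genes with the smallest p in the pooled fit were Cldn4, Elf3, Cdh1 and Tacstd2. Of these, Cldn4, Elf3 and Cdh1 were higher, by log2 fold changes of 1.21, 1.76 and 1.08, and Tacstd2 was lower at -0.56. The remaining called epithelial genes were mostly lower.

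Of 15 Notch pathway genes, 9 were higher in UCS1 FBXW7 and none lower, also adjusted over the list alone, with a mean of 1.21 (camera adjusted p = 4.11e-06; adjusted p = 0.183 with an estimated correlation). They included the Notch target genes Heyl (0.415 ± 0.193 TPM in control and 14 ± 2.11 TPM in FBXW7) and Hey1 (log2 fold change 2.44), and the receptor gene Notch1 (1.65). Of 24 genes whose proteins are listed as FBXW7 substrates, 4 were higher and 2 lower, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.372). With UCS1 fitted alone, 12 of them were higher and 5 lower (camera adjusted p = 0.379). Of 24 TGF-beta response genes, 9 were higher and 2 lower, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.000459; adjusted p = 0.401 with an estimated correlation). Tgfb3 and Id3 were among the higher members, with log2 fold changes of 2.17 and 1.03. Of 30 genes of ribosome biogenesis and MYC targets, none was higher and 12 were lower, or 24 adjusted over the list alone, with a mean of -0.46 (camera adjusted p = 1.42e-09; adjusted p = 0.35 with an estimated correlation). Odc1, the first enzyme of polyamine synthesis, had a log2 fold change of -0.96. Of 30 G1/S and DNA replication genes, 17 were lower and none higher, or 18 adjusted over the list alone, with a mean of -0.30 (camera adjusted p = 4.92e-09; adjusted p = 0.272 with an estimated correlation). Mcm3 had a log2 fold change of -0.53. Of 28 G2/M genes, none was called by limma, over all genes or over the list alone (camera adjusted p = 0.2), and with UCS1 fitted alone 6 were higher and 10 lower (camera adjusted p = 0.144). Of 28 ATF4 and amino acid stress genes, 2 were higher and 11 lower, or 3 and 13 adjusted over the list alone (camera adjusted p = 0.00028; adjusted p = 0.329 with an estimated correlation). Fry passed the Notch (fry adjusted p = 0.000266), G1/S (0.00439), TGF-beta (0.0115), ATF4 (0.0115) and ribosome biogenesis lists (0.0215). It did not pass the substrate (0.0501) or G2/M list (0.648). The 3 tested markers of leukocytes, endothelium and fat were not called.

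The same comparison in UCS2 gave changes that rested on which libraries and which estimate of the spread were used. Col3a1 was at 3.09 ± 1.63 TPM in UCS2 control and 45.2 ± 19.2 TPM in UCS2 FBXW7, and Ogn at 2.18 ± 2.1 and 27.6 ± 5.58 TPM. Pdgfrb, a receptor of mesenchymal cells, was at 1.92 ± 0.77 and 17.1 ± 6.13 TPM. Mgp was at 1.02 ± 0.919 and 44 ± 50.9 TPM. Stmn2 was at 65 ± 21.9 TPM in control and 18.1 ± 0.287 TPM in FBXW7. These 5 genes passed the pooled limma test, and with UCS2 fitted alone none did (adjusted p = 0.0852 for Col3a1, 0.0919 for Ogn, 0.0852 for Pdgfrb, 0.221 for Mgp and 0.131 for Stmn2). With the spread pooled over all 12 libraries, limma called 559 genes higher and 693 lower. The balance turned with the scaling, to 800 higher and 688 lower with median-of-ratios and 854 and 729 with upper quartile. Leaving out 1 library gave from 124 higher and 43 lower without library 8 to 1588 and 3009 without library 12. With the 6 UCS2 libraries fitted alone, limma called 2 genes, Fbln5 and Masp1, both higher (adjusted p = 0.0324 for each), and 1744 genes had an unadjusted p under 0.05. Masp1 was named after its value was seen. On simulated data with each line's own spread and 200 changed genes, 56.4% of the UCS2 calls of the pooled fit were false. The share was 4% when UCS2 was fitted alone, so the pooled UCS2 count is likely to overstate what these libraries show. The false share depends on how many genes change, and the simulated noise was independent between genes. The value of 56.4% need therefore not hold for the measured calls.

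Other genes that the pooled fit placed highest in UCS2 were Serpinf1, Vdr, Aspn, Cd248, Crlf1 and Cbr2, with log2 fold changes of 2.76, 2.7, 2.46, 2.43, 2.31 and 2.28. In the fit of UCS2 alone their adjusted p values were 0.151, 0.0919, 0.189, 0.0919, 0.25 and 0.235. Those placed lowest were Mir3535, Snora81, Lincrna-cox2, Snora70, Cxcl1, Mir17hg, Galnt3, Sdpr and Havcr1, besides Stmn2, and in the fit of UCS2 alone their adjusted p values were between 0.131 for Lincrna-cox2 and 0.332 for Cxcl1. Cxcl1, a neutrophil chemokine, was at 560 ± 109 TPM in control and 273 ± 122 TPM in FBXW7. Mir3535 rested on at most 11 reads per library. In UCS2 FBXW7, Snora81 rested on 8 to 18 reads per library and Snora70 on 8 to 27. With poly-A selection, the values of Mir3535, Snora81 and Snora70 need not reflect the mature small RNAs. In the pooled fit, 10 of 25 extracellular matrix genes were higher and none lower, or 11 adjusted over the list alone (camera adjusted p = 3.08e-09; adjusted p = 0.466 with an estimated correlation). Of 29 mesenchymal genes, 9 were higher and none lower, or 13 adjusted over the list alone (camera adjusted p = 5.38e-07; adjusted p = 0.466 with an estimated correlation). Of 15 Notch pathway genes, 3 were higher, or 4 adjusted over the list alone (camera adjusted p = 0.00269; adjusted p = 0.478 with an estimated correlation), and without library 12 the list no longer passed (adjusted p = 0.0673). Of 10 smooth muscle and pericyte markers, 3 were higher and none lower, or 4 adjusted over the list alone (camera adjusted p = 7.6e-05; adjusted p = 0.478 with an estimated correlation). Of 30 genes of ribosome biogenesis and MYC targets, 3 were lower and none higher, also adjusted over the list alone (camera adjusted p = 0.00177), and without library 9 the list no longer passed (adjusted p = 0.24). Of 30 G1/S and DNA replication genes, 3 were lower and none higher, or 5 adjusted over the list alone (camera adjusted p = 0.00545; 0.147 without library 9 and 0.0737 without library 10). Of 28 G2/M genes, 3 were lower and none higher, or 7 adjusted over the list alone (camera adjusted p = 0.00269; 0.0737 without library 10). For each of these 3 lower lists the adjusted p was 0.611 with an estimated correlation. In the fit of UCS2 alone, Fbln5 was the only called member of any of these lists. Adjusted over the list alone, that fit called 9 matrix, 8 mesenchymal, 1 Notch and 1 pericyte gene higher and no member of the 3 lower lists. Camera at the preset correlation still passed all 7 (adjusted p from 8.5e-10 for extracellular matrix to 0.00797 for G1/S), and no other list test was run in that fit. In the pooled fit, fry passed the matrix and mesenchymal lists (fry adjusted p = 0.00609 and 0.0229). It did not pass the pericyte (0.0654), Notch (0.0946), G1/S (0.0946), G2/M (0.132) or ribosome biogenesis list (0.187). Of 20 epithelial genes, 4 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.297).

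**Figure D2:**
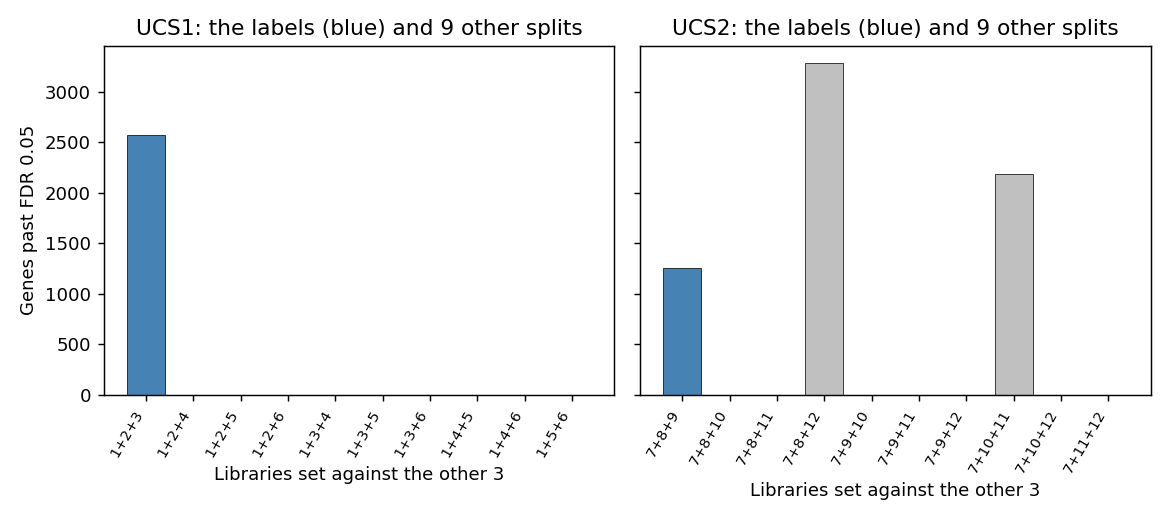
Genes past an FDR of 0.05 in the pooled fit, for the labels (blue) and the 9 other divisions of each line's 6 libraries into 3 and 3 (grey), named by the libraries on 1 side. In UCS1 the labels gave 2574 genes and the highest other division 0, and in UCS2 the labels gave 1252 and the highest other 3289.

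**Figure D3:**
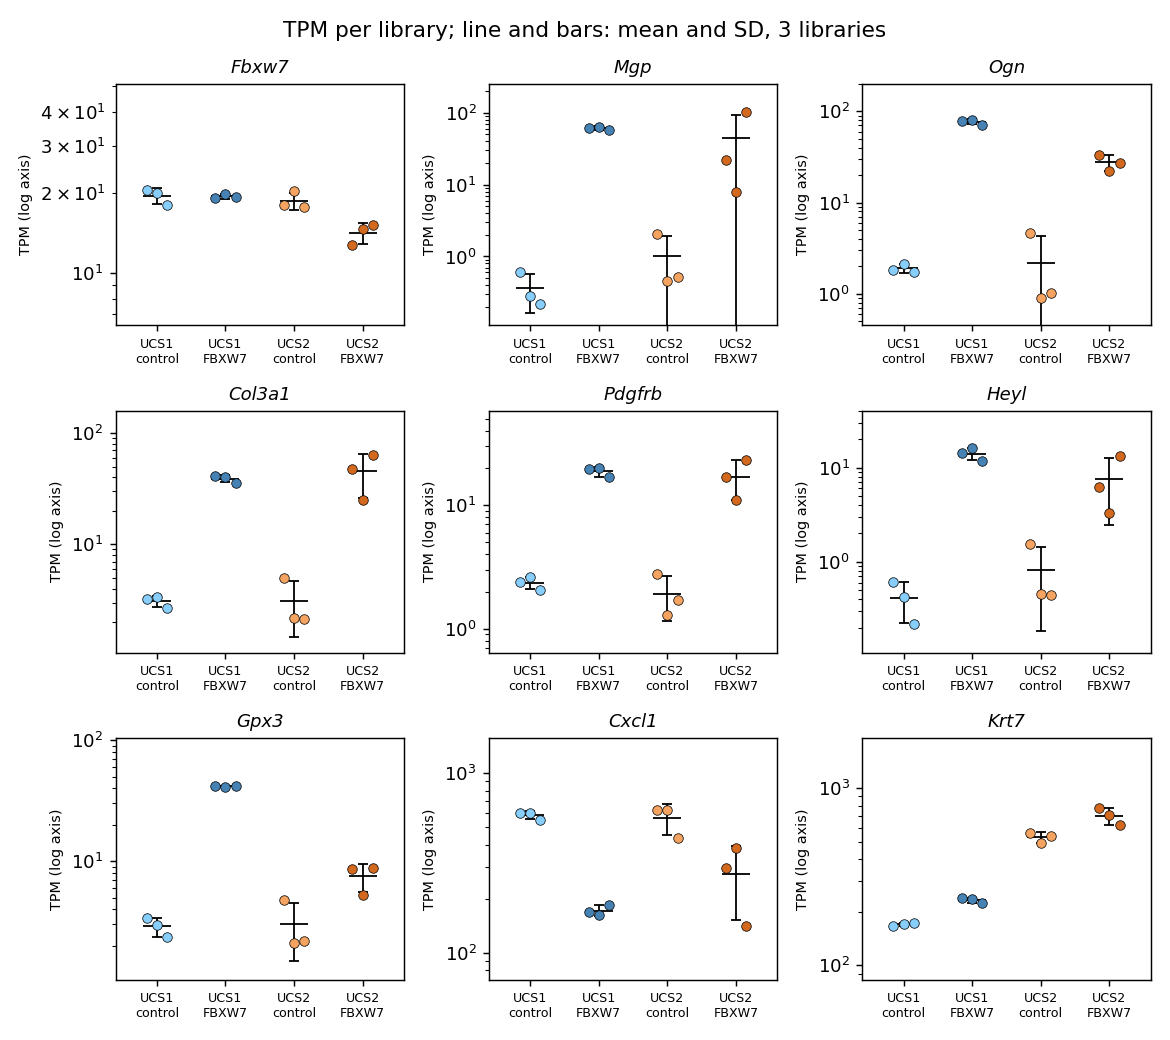
TPM of 9 genes on logarithmic axes, 1 point per library in each of the 4 groups, with horizontal lines at the mean and bars of 1 SD over 3 libraries (a bar that would reach below 0 runs off the axis). Fbxw7 was not higher in the libraries labelled FBXW7, and Mgp was at 61 ± 3.83 TPM in UCS1 FBXW7 but 44 ± 50.9 TPM in UCS2 FBXW7.

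The overlap asked whether the lines changed alike, and the 2 contrasts share no library. In the pooled fit, 382 genes were higher in both lines, against 72.6 for independent lists, and 289 lower in both, against 58.03. Another 5 were called in opposite directions, against 136.81. Both contrasts use the same spread per gene, which the values for independent lists leave out, and another split of the libraries within lines shared 645 calls of the same sign, against 671 for the labels. Leaving out 1 library gave from 107 higher and 30 lower in both without library 8 to 1004 higher without library 7 and 707 lower without library 12, and the opposite calls rose to 226 without library 12 and 26 without library 9. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.66 and rho = 0.58. Of the 2574 UCS1 calls, 91.6% had the same sign in UCS2. The correlations and this share include library 12, which lay nearer to UCS1 FBXW7 than to its own group, and they were not computed without it. With each line fitted alone, 2 genes were called in both lines. Genes higher in both by the pooled fit included Mgp, Ogn, Col3a1, Serpinf1, Pdgfrb, Aspn, Cd248 and Cbr2. Those lower in both included the chemokine genes Cxcl1 and Ppbp, Stmn2, Sdpr, Havcr1, Mir17hg, Mir3535 and Lincrna-cox2. Ppbp was at 839 ± 70.1 and 241 ± 14.7 TPM in UCS1 and at 741 ± 81.4 and 393 ± 114 TPM in UCS2, control first. For the mean of the 2 line effects, limma called 1963 genes higher and 2094 lower, the latter from 1370 without library 1 to 3137 without library 12. In the simulated data 15.4% of the calls for this mean were false, above the share set by the FDR of 0.05.

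The test of the difference between the 2 line effects called 2 genes higher and 7 lower in UCS2 than in UCS1, while 1517 genes had an unadjusted p under 0.05. Gpx3 was higher with the FBXW7 label in UCS1 and stood at 3.01 ± 1.51 and 7.53 ± 2 TPM in UCS2 (limma adjusted p of the difference = 0.0362). Wfdc2, a secreted protease inhibitor of epithelia, was at 153 ± 7.55 and 67.7 ± 3.08 TPM in UCS1 and at 210 ± 12.5 and 256 ± 57.4 TPM in UCS2 (limma adjusted p of the difference = 0.0299). Car12, a membrane carbonic anhydrase, was at 11.5 ± 0.593 and 18.9 ± 0.717 TPM in UCS1 and at 12.2 ± 0.174 and 9 ± 0.346 TPM in UCS2 (limma adjusted p of the difference = 0.00512). Without library 12 the test called 632 and 1507 genes, and without library 7 it called 12 and 15. Without each of the other 10 libraries it called 0 higher and 2 or 3 lower. The calls of Gpx3 and Wfdc2 were lost each time (adjusted p up to 0.165 and 0.149), and that of Car12 held in all 12 fits.

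The control libraries of the 2 lines were compared as background, with 1 line on each side. UCS2 control had more of several epithelial transcripts. Krt7, a keratin of simple epithelia (chromosome 15, 101411043 to 101430313, mm10), was at 170 ± 3.99 TPM in UCS1 control and 528 ± 35.3 TPM in UCS2 control. Epcam was at 1.67 ± 0.229 and 6.07 ± 0.935 TPM, and Cldn3, a tight-junction gene, at 4.82 ± 0.977 and 15.5 ± 1.35 TPM. By limma, 9 genes were higher and 4 lower in UCS2 control. Of 20 epithelial genes, 5 were higher and none lower, or 8 adjusted over the list alone, with a mean log2 fold change of 0.66 (camera adjusted p = 1.12e-20; adjusted p = 0.0395 with an estimated correlation). Of 29 mesenchymal genes, none was called, or 2 lower adjusted over the list alone, with a mean of -0.30 (camera adjusted p = 0.00498; adjusted p = 0.84 with an estimated correlation), and without library 7 the list no longer passed (adjusted p = 0.189). Fry passed the epithelial list and not the mesenchymal one (fry adjusted p = 0.00169 and 0.751). Stra6, Sprr1a and Il18r1 were also higher in UCS2 control, with log2 fold changes of 1.72, 1.38 and 1.02. Egln3, Mrc2 and Ebf3 were lower, with -0.93, -0.90 and -0.68. Without library 12, which alters the pooled spread, the counts were 50 and 66, and without library 7 they were 11 and 15. Without each of the other 10 libraries they were 5 to 8 higher and 1 to 3 lower. Krt7, Epcam, Cldn3 and Stra6 were called in all 12 fits, while Sprr1a, Il18r1, Egln3, Mrc2 and Ebf3 lost the call in 10 or 11 of them.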

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

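The tests of wrong labels, mixed cells, fibroblasts, the standard errors and the size of the response were chosen after the results they bear on were seen, and the YAP list was written after YAP target genes had been noticed. The difference between the 2 line effects, tested as an interaction, singled out 9 named genes. Its log2 values, UCS2 effect minus UCS1 effect, were -2.34 for Gpx3, 1.43 for Wfdc2, 0.78 for Tinagl1, -1.09 for Cx3cl1, -1.08 for Car12, -0.97 for Lsp1, -0.93 for Gdpd5, -0.73 for Cables1 and -1.74 for Emilin1. Only Car12 and Emilin1 kept the call in all 12 fits with 1 library left out, and each of the others lost it in 10. The difference between the line effects, tested by camera, singled out 7 lists, whose mean differences were -0.44 for extracellular matrix, -0.78 for the Notch pathway, -0.49 for TGF-beta response, 0.17 for ribosome biogenesis and MYC targets, 0.12 for G1/S and DNA replication, 0.24 for hypoxia and glycolysis and 0.19 for ATF4 and amino acid stress. None of the 7 passed with an estimated correlation (adjusted p from 0.397 to 0.762) or with fry (fry adjusted p from 0.0884 to 0.589). Of 100 splits within lines, 14 called at least the 9 genes that the labels gave for this difference, and the highest other split called 2962, so chance cannot be excluded. Exchanging the labels of 1 line turns the difference into a sum of effects, which raises some of these splits. Any split that keeps the UCS1 grouping and regroups UCS2 also carries the UCS1 effect into the difference. The 14 splits therefore cannot measure how often chance alone gives such calls.

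Other splits of the libraries showed how far each count stands out. In UCS1, 1 of 10 splits, the labels themselves, called 2574 genes, and the highest other split called 0. In UCS2, 3 of 10 splits called at least the 1252 genes of the labels, and the highest other split called 3289. That split set libraries 7, 8 and 12 against 9, 10 and 11, and a further one, libraries 7, 10 and 11 against 8, 9 and 12, called 2190, which points to a structure among the UCS2 libraries that the labels do not describe. Between control lines, 1 of 10 splits called the 13 genes, and the highest other called 0. A set of 10 splits is too few for a share under 0.05. For the mean effect, 1 of 100 splits within lines reached 4057 genes, with 3856 the highest other. For genes called in both lines with the same sign, 1 of 100 reached 671, with 645 the highest other. The labels gave the highest of 100 for these 2 counts, by a narrow margin in each. These splits regrouped both lines at once, and every other split of UCS1 alone called 0 genes. The shares may thus largely restate the UCS1 grouping, and they do not exclude chance in UCS2 or in the sharing between lines.

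The first pattern is the place of UCS2 libraries 12 and 8 near UCS1. On the 13 genes called between control lines, library 12 lay 77.6% of the way from UCS1 FBXW7 to libraries 10 and 11 (95% bootstrap interval over genes 71.8 to 83.4; 28.6% over all tested genes), and the UCS1 FBXW7 libraries themselves lay between -0.9% and 2.3%, which argues against a UCS1 library under a wrong label. The share of UCS1 that mixed cells would need was 53.5 points lower on those genes than on the 552 genes at least 2-fold apart, which were picked for that distance; over all tested genes it was 66.8%, against 34% on the line genes, so mixing alone does not account for the position, although a smaller share of UCS1 cells stays open. On the 9 genes called between control lines without library 8, that library lay 79.9% of the way from UCS1 control to libraries 7 and 9 (95% bootstrap interval 72.3 to 86.4), and the UCS1 control libraries lay between -1.3% and 1.5%, which argues against a UCS1 library under a wrong label; on the 3784 genes called between the FBXW7 arms it lay at 45%, against -4.9% to 18.4% for the UCS1 controls, and mixed cells were not tested there. The median of 19 YAP target genes in library 12 was 0.40 log2 units above libraries 10 and 11, at the 99.7th percentile of 10000 matched random lists, but random genes are not co-regulated as list members are, so the place of both libraries stays unexplained.

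The second pattern is the smaller number of calls in UCS2, which turned round without library 12, at 1588 higher and 3009 lower in UCS2 against 2123 and 1611 in UCS1. In the pooled fit the standard errors of both contrasts are equal by design (median ratio 1), and on simulated data that fit recovered 86.6% of changes of a log2 of 1 in UCS2 and 86.4% in UCS1 but made 219.4 and 1 false calls, so there the spread raised the UCS2 count. With each line alone the recovery was 56% and 98.6%, so spread stays open for the lower count of that fit. Along the UCS1 response, libraries 10, 11 and 12 stood at 50.8%, 28.4% and 65.3%, measured from the mean of all UCS2 controls. Controls 7, 8 and 9 stood at 31.4%, -16.9% and -14.5%, each measured from the remaining UCS2 controls. Leaving a control out of its own zero point stretches its distance. Measured from the mean of all UCS2 controls, each control would therefore stand nearer to the zero point. On that common zero point libraries 10, 11 and 12 all stood above the controls, by the least for library 11 over control 7. With 3 libraries per group this order does not exclude chance. Measured from controls 8 and 9 alone, library 12 stood at 75.7%, past the bound of 75% set for a smaller response in each library, so that explanation stays open too.

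For the third pattern, the rise of matrix and pericyte genes, the median rise of 6 abundant fibroblast transcripts in UCS1 was 5.2% of the rise of Col3a1, which argues against fibroblasts in the cultures as the whole source. Col1a2, Dcn and Lum stood at 0.409, 0.401 and 0.0107 TPM in UCS1 FBXW7, while Sparc and Postn, of the same list, rose by 271 and 510 TPM. Pericytes stay open: of their markers, Rgs5, Kcnj8 and Abcc9 stood at 2.12, 0.0199 and 0.015 TPM there, too low to decide. Drift of separately transduced populations had been predicted absent if fewer than 1 in 20 splits shared as many calls, and 1 of 100 did, but it stays open, since regrouping libraries cannot test this, because each arm may be 1 transduced population and arm and population then coincide. A change in the tumour cells themselves remains a hypothesis.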

How the results depend on the processing

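The settings without libraries 7 and 12, with group variance weights, without genes under 200 bp and with the lists in each line alone were chosen after seeing the data. No paired analysis was possible because the columns carry library numbers and not the replicate numbers of the labels. Of the planned tests on counts, limma-voom was run on the recovered reads, with their totals as library sizes. TMM, the quasi-likelihood test and DESeq2 were not run. The TPM of each library sum to the same total, so scaling by that total leaves the main values unchanged. The cause was not tested except where fewer libraries or a stricter threshold make it plain. Every UCS1 list call held when each library was left out. In UCS2 the extracellular matrix, mesenchymal and pericyte list calls also held, and those for ribosome biogenesis, G1/S, G2/M, Notch, hypoxia and interferon were each lost without at least 1 library.

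With each line alone, 4221 genes were higher and 3304 lower in UCS1, 2 and 0 in UCS2, and 2 higher, 0 lower and 0 opposite in both. With group weights these were 4258 and 3406, 51 and 5, and 48, 5 and 1, with 4 higher for the difference. At an FDR of 0.01 the counts were 707 and 277 in UCS1, 122 and 42 in UCS2, 1060 and 864 for the mean effect, 0 and 2 for the difference, 5 and 1 between controls, and 95, 21 and 1 for the overlap. With a 2-fold minimum they were 385 and 107, 108 and 13, 238 and 64, 1 and 4, 0 lower between controls, and 86, 7 and 0. Without libraries 7 and 12 they were 3296 and 2273, 2980 and 3326, 3778 and 3483, 1334 and 2022, 115 and 326, and 1627, 1194 and 429. Those libraries were picked for their distance, which lowers the spread by construction, so the higher counts are no evidence of a larger effect. Upper quartile scaling gave 854 higher in UCS2 and 0 higher for the difference. Without a filter 427 were lower in UCS2, 5 and 53 for the difference, and 17 and 7 between controls. The stricter filter gave 4 and 1 between controls. Limma-voom gave 0 and 3 for the difference and 9 lower between controls. Median-of-ratios scaling gave 3 opposite.

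Leaving out 1 library gave 784 to 2238 higher and 341 to 1611 lower in UCS1, 124 to 1588 and 43 to 3009 in UCS2, 1370 to 3137 lower for the mean effect, 0 to 632 and 2 to 1507 for the difference, 5 to 50 and 1 to 66 between controls, and 107 to 1004, 30 to 707 and 2 to 226 for the overlap. The lowest UCS2 counts came without library 8. The highest lower count there, both of the difference and both between controls came without library 12. Scaling moved the share of higher calls between controls from 69.2% to 81.2% with median-of-ratios and for the difference from 22.2% to 0% with upper quartile, and the median difference from -0.099 to 0.017.

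The results below changed sign, or for lists the direction of their test, so some ranges of means keep 1 sign. Between controls the sterol, interferon and AP-1 lists had passed camera (adjusted p = 0.000207, 0.0179 and 0.0405, and 0.84 for each with an estimated correlation). The others had not passed. The AP-1 call between controls was lost without library 2 (camera adjusted p = 0.0624) or 3 (0.181). Ranges are over leaving out 1 library. Fbxw7 in UCS1 ran from -0.056 to 0.035 and Pten in UCS2 from -0.311 to 0.116 (0.138 without 7 and 12). UCS2 list means ran from -0.18 to 0.27 for AP-1 (-0.37 without 7 and 12), -0.05 to 0.09 for ATF4 (0 without a filter, 0.01 with fry), -0.09 to 0.31 for TGF-beta (-0.16), -0.12 to 0.15 for epithelial (-0.08 without a filter), -0.11 to 0.07 for p53 (-0.03), -0.15 to 0.07 for histones (0 without a filter, 0.13) and -0.13 to 0.28 for sterol (0.01 with fry). Between controls they ran from -0.38 to -0.06 for AP-1 (-0.06), -0.21 to 0.09 for FOXO, -0.06 to -0.01 for G1/S (-0.03 with fry), -0.14 to 0.03 for chondrogenic (-0.02 without a filter), -0.02 to 0.04 for hypoxia, -0.11 to 0.28 for interferon (-0.11), -0.14 to 0.03 for p53, -0.21 to 0.04 for ribosome biogenesis (0.04) and -0.08 to 0.33 for sterol (-0.08), where a bare value in parentheses is without libraries 7 and 12.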

Other observations

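Beyond the genes described for the line comparisons, UCS1 FBXW7 libraries had more transcript of several bone and interferon genes. Of 6 tested chondrogenic, osteogenic and myogenic genes, 4 were higher and none lower, or 5 adjusted over the list alone (camera adjusted p = 0.00326; adjusted p = 0.183 with an estimated correlation), with Spp1, which encodes osteopontin, at a log2 fold change of 1.67 and Alpl at 1.47. Of 21 interferon response genes, 5 were higher and none lower (camera adjusted p = 0.00583; adjusted p = 0.643 with an estimated correlation), among them Ifit1 at 1.33 and Psmb8 at 0.88. Of 14 FOXO targets, 4 were higher and 1 lower (camera adjusted p = 0.0205; adjusted p = 0.467 with an estimated correlation), with Txnip at 1.15. Of 31 sterol and fatty acid synthesis genes, 3 were higher and none lower, but none adjusted over the list alone (camera adjusted p = 0.0139; adjusted p = 0.653 with an estimated correlation), and 27 were higher and 3 lower with UCS1 fitted alone. Fry passed the chondrogenic and FOXO lists (fry adjusted p = 0.000266 and 0.0195) and not the interferon and sterol lists (0.126 and 0.256).

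Other lists did not pass camera in UCS1. Of 23 inflammatory NF-kB targets, 2 were higher and 6 lower (adjusted p = 0.218), with Cxcl1 and Cxcl2 at log2 fold changes of -1.76 and -1.88 and Ccl5 at 1.20. Of 24 hypoxia and glycolysis genes, 2 were higher and 4 lower, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.218), with Egln3 at -1.47. AP-1 and immediate early genes gave 3 higher and 2 lower of 26, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.451), p53 targets 2 higher of 22 (camera adjusted p = 0.171), uterine identity genes 3 higher and 1 lower of 10 (camera adjusted p = 0.451), and replication-dependent histones 1 higher and 1 lower of 16, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.322). For the other lists above, the counts were the same adjusted over the list alone. Esr1, the oestrogen receptor gene of the uterine list, had a log2 fold change of 1.61.

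In UCS2, 2 further lists passed camera in the pooled fit and with UCS2 fitted alone (camera adjusted p there = 0.0306 for hypoxia and 0.0108 for interferon). No member of either was called over all genes with UCS2 fitted alone. Adjusted over the list alone, that fit called 1 interferon gene higher and no hypoxia gene. The counts below are from the pooled fit. Of 24 hypoxia and glycolysis genes, 4 were higher and none lower, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0266; adjusted p = 0.597 with an estimated correlation). This call was lost without library 7 (adjusted p = 0.184), 10 (0.0737) or 11 (0.16). Of 21 interferon response genes, 1 was higher and none lower, also adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.639 with an estimated correlation). This call was lost without library 8 (adjusted p = 0.079), 9 (0.121) or 10 (0.134). Neither list passed fry (fry adjusted p = 0.187 for hypoxia and 0.398 for interferon).

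Between control lines, 3 further lists passed camera as higher in UCS2 with no member called over all genes, and for each the adjusted p was 0.84 with an estimated correlation. The ATF4 list (camera adjusted p = 0.0294) lost the call without library 2 (0.0644), 8 (0.254) or 9 (0.644). The NF-kB list (camera adjusted p = 0.0383) lost it without library 3 (0.0532), 7 (0.0872) or 9 (0.0713), and the histone list (camera adjusted p = 0.0394) without library 1 (0.147), 7 (0.0872) or 9 (0.199). Adjusted over the list alone, none, 1 and 1 of their genes were higher. None of these lists passed fry (fry adjusted p = 0.751 for each).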
